A study of Mus musculus with 105 samples.

How the data were processed

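Ribosome footprints (Ribo-seq), polyadenylated mRNA (Smart-seq2) and poly(A) tail lengths (full-length cDNA on a PacBio Sequel II) were measured in mouse oocytes. The labels describe 105 samples, of which 53 had values in the 3 deposited tables. The remaining 52 samples, among them embryos and Cnot6l mutants, were not analysed here. The samples used were 18 single full-grown oocytes (FGO) and 20 single metaphase II (MII) oocytes with footprints, MII oocytes of Btg4 heterozygous (Het) and knockout (KO) genotype with footprints (3 and 3 libraries) and mRNA (2 and 2 libraries), and 5 tail libraries (FGO wild type, MII wild type and MII Btg4 Het with 1 each, MII Btg4 KO with 2). Per the labels' protocols, oocytes came from C57BL/6 females given gonadotropins. For footprints, lysates with cycloheximide were digested with RNase I and ribosomes were pelleted through a sucrose cushion. For tails, total RNA was end-extended with oligonucleotides before reverse transcription. The tail library of FGO is labelled SN and the single FGO are not, so these FGO may differ in kind.

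Footprint and mRNA values are FPKM per gene as deposited by the authors. Per the submitters' processing notes the tools were cutadapt 1.14, Trim Galore 0.4.2, Bowtie2 2.2.2, STAR 2.5.3a and Cufflinks 2.2.1, and the builds mm9 and hg19, with no role given for each. No spike-in is named in the labels, so FPKM are relative to each library's own total. Tail lengths are in nucleotides per gene as deposited by the authors, with 0 where a gene had no value. The tail caller, the minimum of reads and the way reads were summarised per gene are not given in the sources used here. The tables also hold the authors' averages of the Btg4 libraries, which were not used, and merged tail columns, whose values are given only as the authors'.

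Both FPKM tables hold 20756 genes after 231 exact repeats were dropped from the Btg4 table. Of the tail table's names 24 looked like dates. Of 6443 genes with a tail value, 6340 were matched to an FPKM gene, 24 of these through a synonym in the GRCm38.p6 annotation, and 103 were not matched. No coordinates were used. Low footprint values were compared with whole multiples of the value of 1 read. With a tolerance of 0.03 reads and below 12 reads, 78.5% of values were whole. Reads could be recovered for 7886 genes, which hold 28.5% of footprint FPKM, so the recovered totals measure relative depth only and no count model was used. The depth of the mRNA and tail libraries is unknown.

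Btg4 KO was compared with Het by limma 3.58.1 in R 4.3.3 (lmFit, eBayes with trend) on log2(FPKM + 1), two-sided, with Benjamini-Hochberg adjusted p below 0.05 as the threshold. Genes needed a mean of at least 1 FPKM over the libraries of the fit. Translational efficiency was tested as the interaction of genotype and assay over all 10 libraries, for genes with a mean of at least 1 FPKM in both assays. This fit, and its simulation below, take the spread of a gene as the same in both assays. Libraries of the same genotype correlated at 0.958 and 0.966 in mRNA and at 0.699 to 0.815 in footprints. A fold change on the log2(FPKM + 1) scale understates the change of low genes. Adjusted p-values in the text are from these limma fits unless another test is named. Tail lengths were fitted with limma over all 5 libraries, which leaves 1 residual degree of freedom, from the KO pair. This fit assumes that single libraries vary like that pair. In single oocytes each oocyte is a cell and the labels name no animals, so each stage counts as 1 sample and no test was made. The values are log2 of (mean FPKM + 1) in MII over FGO, the SD between oocytes, and for each gene list the percentile of its median among 10000 random lists of the same size matched on mean level in 20 bins. Spearman rho across genes describes relations between measures without a p-value, since genes are not independent replicates. The labels name no separate animals or cultures for the Btg4 libraries, so p-values measure only the spread between these samples, which may be technical. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used for the other steps.

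The tests, the 15 gene lists, the rule for named genes and all alternatives not described as added were chosen before the data were examined. The lists are maturation-activated maternal mRNAs, mRNA deadenylation and decay, oocyte growth and zona pellucida, the subcortical maternal complex and maternal effect genes, RNA storage and translational control, polyadenylation, cytosolic ribosomal proteins, the nuclear-encoded mitochondrial respiratory chain, proteasome, meiotic cell cycle and spindle, translation factors, chromatin and DNA methylation regulators, 2-cell and zygotic activation genes, and markers of somatic follicle cells and of blood and immune cells. Lists with at least 5 tested members were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists of a fit. Named genes are Btg4, then the 10 largest rises and 10 largest falls per limma comparison among genes past the threshold with a mean of at least 10 FPKM and, except for efficiency, no overlap between KO and Het libraries. For tails they are the 10 largest gains and losses per contrast among genes measured in all 5 libraries with at least 10 FPKM of Het mRNA. For single oocytes they are the 10 largest ratios each way among genes with at least 10 FPKM and a value above 0 in at least as many oocytes of that stage as are at 0. Up to 4 members per list with the smallest adjusted p, or the largest difference where there was no test, could be named. Predicted genes could be left unnamed. Other genes that are named were chosen after their values were seen.

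In the footprint libraries, deviations from the group means correlated across genes with r of 0.255, 0.422 and 0.162 between Het and KO libraries of the same number. Every value is over 0.1, so the numbers were taken to pair the footprint libraries. Between libraries of different numbers r lay between -0.319 and 0.0977, and the highest of these is close to the lowest same-number value. This pairing comes from the data and not from a label. The blocked count is given beside a result where it changes the call or moves the count by over 1.5 times.

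Each fit was tested on simulated data with known changes. The noise was drawn with limma's moderated SD, a choice made after a first version with raw residual SD was seen to exaggerate the differences in spread between genes. In the mRNA comparison (8670 simulated genes) 13 of 67 genes changed 2-fold were called, 63 of 67 at 4-fold and 66 of 66 at 8-fold, with 10 unchanged genes called. In the footprint comparison (7950 genes) the counts were 0 of 67, 5 of 67 and 26 of 66, with 2 unchanged genes called. In the efficiency comparison (6890 genes) they were 0 of 67, 1 of 66 and 1 of 66, with 2 unchanged genes called. The power for footprints and efficiency is therefore low. In these comparisons changes were planted only in genes whose mean log2(FPKM + 1) lay above that of 10 FPKM. The power for lower genes was not measured. In the tail fit, with 600 genes of the same SD, a shift of 10 nt was called for 11 of 50 genes, 20 nt for 30 of 50 and 40 nt for 50 of 50, with 2 of 400 unshifted genes called. The real fit has less power. With 129 genes and the spread between genes taken from it, in 200 simulations added after seeing the data, 3% of shifts of 40 nt and 15% of 80 nt were called, and 155 simulations gave 0 calls. A count of 0 in the tail fit therefore does not show that tails were unshifted. Among simulated lists of 20 genes, 5% of random ones lay outside the central 95% and 51% of lists shifted up by 1 log2 unit lay above it. The 5% was fixed in advance, since these lists were drawn from the same genes as the random lists. The percentiles do not allow for genes of a list that vary together, which can make them too extreme.

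Alternatives covered the pseudocount, filters on low values, quantile and median scaling between libraries, the replicate block, each library left out in turn, limma without trend, a 2-fold minimum, other controls for tails, other summaries of oocytes, and other list tests. A check of gene length was not made.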

Results

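The data describe translation, mRNA levels and poly(A) tails while mouse oocytes mature from the full-grown stage (FGO) to metaphase II (MII), and the effect of losing Btg4, an adaptor of the CCR4-NOT deadenylase. Genes with at least 1 FPKM numbered 4338 to 8826 per single FGO (18 oocytes, median 6477) and 3645 to 6351 per single MII oocyte (20 oocytes, median 4759.5). Recovered footprint reads, over the genes where reads could be recovered, numbered 17642 to 154420 per FGO and 8543 to 44069 per MII oocyte. In the Btg4 footprint libraries they numbered 188574, 101859 and 60850 in Het and 100281, 176558 and 149915 in KO. The Btg4 mRNA libraries listed 7959 to 8494 genes at 1 FPKM or more in Het and 8814 to 9151 in KO. Tail lengths were given for 6353 genes in FGO wild type, 229 in MII wild type, 598 in MII Het, and 867 and 1416 in the MII KO libraries.

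Btg4 mRNA measured 3293 and 4774 FPKM in the Het libraries and 1754 and 2345 FPKM in the KO libraries, which is 4033 ± 1048 against 2050 ± 417 FPKM (SD, n = 2 each). The log2 change was -0.97 (SE 0.35, adjusted p = 0.0889, limma), short of the threshold. Btg4 footprints measured 7009, 6346 and 6134 FPKM in Het against 1148, 971 and 907 FPKM in KO, and fell by 2.69 on the log2 scale (SE 0.23, adjusted p = 0.00654, limma). Btg4 was listed above 0 in every KO library, and the values went in the direction of the genotype labels. Which part of the gene the mutation removes is not given in the sources used here, so reads outside that part check nothing. Footprint efficiency of Btg4 had a log2 change of -1.72 (SE 0.37, adjusted p = 0.0672, limma), which passed the threshold with the replicate block. In single wild-type oocytes Btg4 footprints were 12.3 ± 22.6 FPKM in FGO and 2056 ± 850 FPKM in MII (mean ± SD between oocytes).

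**Figure D1:**
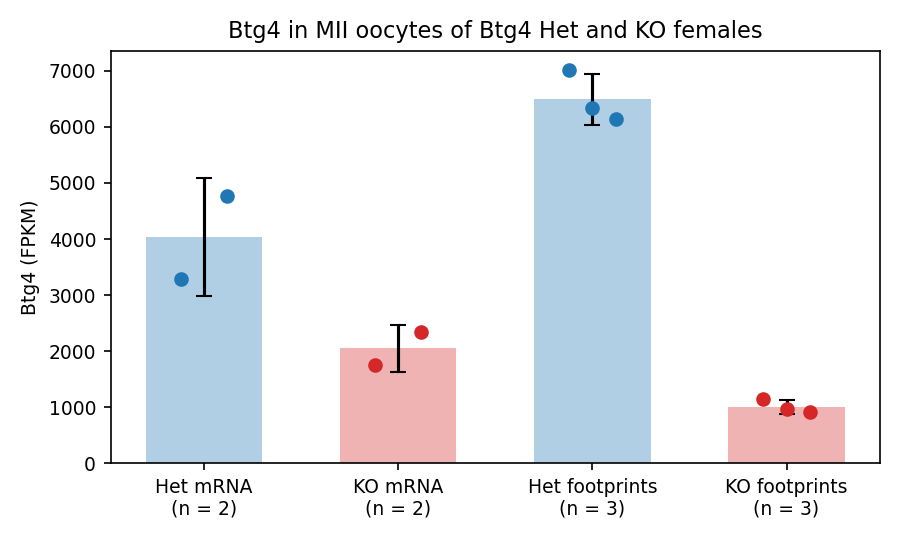
Btg4 level in FPKM in the mRNA (n = 2 per genotype) and footprint (n = 3 per genotype) libraries of MII oocytes, with bars for the mean, error bars for the SD and points for the libraries. The KO footprint libraries lie between 907 and 1148 FPKM and the Het ones between 6134 and 7009 FPKM.

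To see which messages gain or lose ribosomes during maturation, footprints of single MII oocytes were set against those of single FGO. Omt2a, an oocyte-specific maturation gene, was at 8.27 ± 22.1 FPKM in FGO and 3474 ± 1391 FPKM in MII, a log2 ratio of 8.55. Its relative Omt2b had a log2 ratio of 8.34, the Bcl-2 family gene Bcl2l10 one of 8.14, and the oocyte-secreted protein gene Oosp3 one of 7.85. The 5 genes Tcl1b1, Tcl1b5, Tcl1b4, Tcl1b2 and Tcl1b3, relatives of the Akt co-activator Tcl1, had ratios between 7.65 and 8.29, and the X-linked AU022751 (Ezhip) one of 7.80. Each of these 10 genes was higher in every MII oocyte than in every FGO (100% of oocyte pairs). Tcl1b genes and the Omt2 pair are similar copies, so the split of reads between them is uncertain. At the other end, Tmsb4x, which encodes the actin-binding thymosin beta 4, was above 0 in 9 of 18 FGO, with a highest value of 13528 FPKM, and listed at 0 in all 20 MII oocytes. S100a2, Hao2, Upk2, Asdurf, Tceal9 and Cstb were above 0 in 9 to 17 FGO and also listed at 0 in every MII oocyte. Galr3 (2 of 20 MII oocytes), Rps27rt (2 of 20) and Ube2m (3 of 20) were above 0 in nearly all FGO, with log2 ratios of -6.69, -4.56 and -4.31. Since each stage counts as 1 sample, none of these differences was tested.

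Maturation-activated maternal mRNAs, a list of messages known to be recruited for translation during meiosis, had a median log2 ratio of 5.21 over 20 members (percentile 100 of matched random lists). Plat, the tissue plasminogen activator, went from 10.8 to 2061 FPKM. The deadenylase gene Cnot7 went from 4.20 to 681 FPKM and the decapping factor gene Dcp1a from 3.72 to 460 FPKM. In the meiotic cell cycle list (31 members, median 1.05, percentile 92.0) Bub1b, Ccnb1, Cdc20 and Fbxo43 had ratios of 5.92, 5.53, 5.35 and 5.06. The deadenylation and decay list had a median of 0.21 (27 members, percentile 78.7), with Pan2 at 5.37 and Cnot8 at 5.07. Polyadenylation factors had a median of 0.22 (17 members, percentile 69.4), led by Cstf1 at 3.10 and Wdr33 at 2.45. Chromatin and DNA methylation regulators had a median of -0.06 (25 members, percentile 42.6), although the DNA demethylation enzyme gene Tet3 had 4.79, the Polycomb gene Eed 4.15, Kdm6a 3.31 and the oocyte linker histone gene H1foo 2.89.

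Genes of general growth metabolism went the other way. Cytosolic ribosomal protein genes had a median of -2.15 (77 members, percentile 0), with Rpl38 at 987 ± 646 FPKM in FGO and 76.0 ± 145 FPKM in MII. Nuclear-encoded respiratory chain genes had a median of -1.97 (73 members, percentile 0), with Atp5g1 at -4.18 and Ndufb5 at -3.92. Proteasome genes had a median of -1.35 (36 members, percentile 0.11), with Psmb5 at -3.04 and, against the list, Psmd3 at 2.90. Translation factors had a median of -1.20 (32 members, percentile 0.72), with Eef1a1 at -2.49 and Eif1ax at -2.39. The list of subcortical maternal complex and other maternal effect genes, called the subcortical maternal complex list below, had a median of -1.47 (17 members, percentile 1.94). In it Ooep stood at -2.60 and Tle6 at -2.33, while Zbed3 was at 4.67 and Trim28 at 3.02. The oocyte growth and zona pellucida list had a median of -1.47 (14 members, percentile 2.40), with Oosp1 at 6.70 and the transcription factor gene Figla at -3.70. RNA storage factors had a median of -0.42 (19 members, percentile 18.9), with Pabpn1l at 4.48, Dazl at 4.18 and Ybx2 at -3.41. The 3 measured 2-cell genes had a median of -1.05 (percentile 21.1), with Arg2 at -2.24.

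Some markers of other cells differed between the stages too. Blood and immune markers had a median log2 ratio of -2.18 (10 members, percentile 0.02). Hba-a1 and Hba-a2, hemoglobin genes with identical values, were above 0 in 8 of 18 FGO and 1 of 20 MII oocytes. Hbb-b1 and Hbb-b2 were above 0 in 6 of 18 FGO and in 0 of 20 MII oocytes. Follicle cell markers (15 members, percentile 5.21) had a median level of 2.75 FPKM in FGO and 1.25 FPKM in MII, with Inha above 0 in 13 of 18 FGO and 1 of 20 MII oocytes, and Gja1, a gap junction protein gene of granulosa cells, in 17 of 18 and 5 of 20. The median over FGO was 0 for each of the 4 hemoglobin genes. Serpine2, in the follicle cell list, was higher in MII, at 4.51. Without the oocytes that list a hemoglobin gene, a comparison added after seeing the data that leaves 9 FGO and 18 MII oocytes, the list medians were -1.85 for ribosomal proteins, -1.73 for the respiratory chain, -1.08 for the proteasome and 5.25 for maturation-activated mRNAs. The median over all 10068 genes moved from -0.26 to 0.04 and the blood list from -2.18 to 0.19. The 4 hemoglobin genes are at 0 in the remaining oocytes by selection, so the move of the blood list was partly fixed in advance.

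Across genes the median Spearman correlation was 0.564 between FGO (0.394 to 0.804), 0.574 between MII oocytes (0.38 to 0.684) and 0.289 between the stages (0.151 to 0.655). MII oocytes 2 and 4 had higher median correlations with FGO (0.534 and 0.551) than with the other MII oocytes (0.516 and 0.487), which was so for 0 of the other 36 oocytes. Ooep stood at 1868 and 3418 FPKM in these 2 oocytes and between 13.9 and 278 FPKM in the other 18 MII oocytes. Rpl38 stood at 531 and 359 FPKM against 0 to 249 FPKM, and Eef1a1 at 158 and 259 FPKM against 0 to 107 FPKM. Plat, high in MII, was at 1960 and 721 FPKM in them. Without these 2 oocytes, a comparison added after seeing the data, the highest correlation between the stages was 0.392 and the log2 ratio of Ooep -4.14 (131 ± 88.7 FPKM in MII). The list medians were then -2.62 for ribosomal proteins, -2.51 for the respiratory chain, -1.71 for the proteasome, -1.99 for the subcortical maternal complex, -2.11 for oocyte growth, -0.57 for chromatin, -1.83 for the 2-cell genes and 5.30 for maturation-activated mRNAs. With 1 oocyte left out, some ratios given above moved by over 1.5 times. Without MII oocyte 4 they were -3.38 for Ooep, -5.29 for Rps27rt, -5.15 for Atp5g1 and -3.48 for Eif1ax. That of Galr3 was -7.37 without MII oocyte 1, that of Omt2a 9.62 without FGO 18 and that of Pabpn1l 5.30 without FGO 3.

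**Figure D2:**
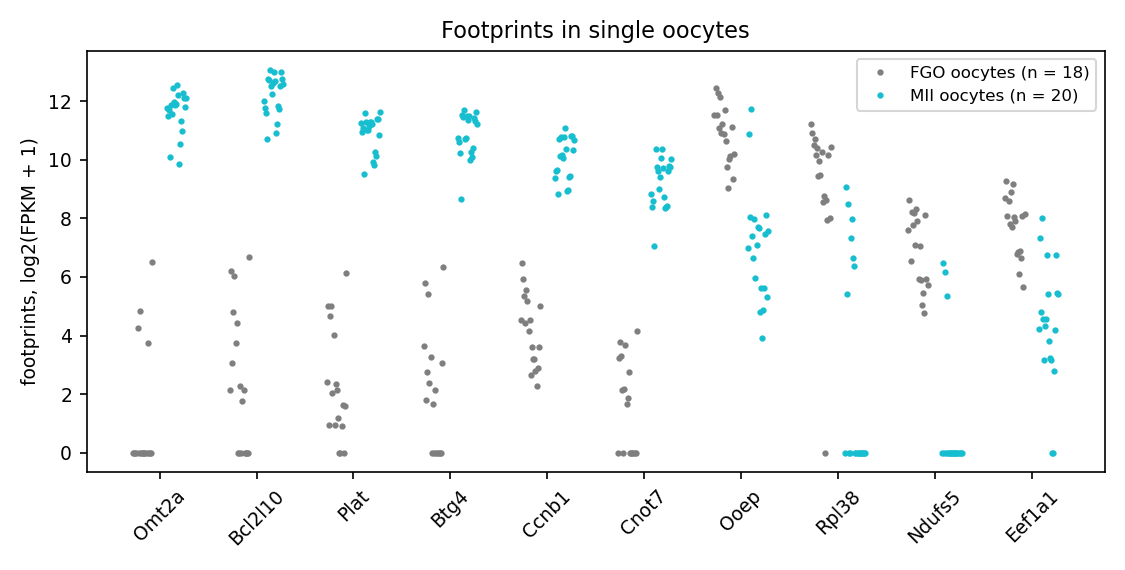
Footprints of 10 genes, chosen after their values were seen, in single FGO (18 oocytes) and MII oocytes (20 oocytes), as log2(FPKM + 1), with 1 point per oocyte. Omt2a, Bcl2l10, Plat, Btg4, Ccnb1 and Cnot7 lie higher in MII oocytes, and Ooep, Rpl38, Ndufs5 and Eef1a1 lie lower on average, with MII oocytes 2 and 4 at 1868 and 3418 FPKM of Ooep.

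The loss of Btg4 was first examined in mRNA. In KO oocytes 1677 of 8865 tested genes rose and 55 fell (limma, adjusted p below 0.05). Psmb7, a catalytic proteasome subunit gene, went from 2.00 ± 0.231 to 291 ± 22.7 FPKM (SD, n = 2), a log2 change of 6.60 (SE 0.31, adjusted p = 0.000123). Another proteasome gene, Psmb1, rose by 5.57, the ribosomal protein gene Rpl18 by 5.58, the cytochrome oxidase gene Cox7c by 5.72, the oxidase assembly gene Cox17 by 5.36, and the mitochondrial Chchd2 by 5.56 on the log2 scale. Khdc3, a member of the subcortical maternal complex, rose from 22.6 ± 6.09 to 905 ± 84.4 FPKM (log2 change 5.29). Dppa5a, an RNA-binding protein gene of oocytes and pluripotent cells, rose by 5.08 and Ccdc58 by 5.35. The falls were smaller. Lzts1 had a log2 change of -2.36 (SE 0.44, adjusted p = 0.00804), the cytokine gene Il17f -1.82, the zinc finger gene Zfp979 -1.63, the sialic acid enzyme gene Cmas -1.54, Steap2 -1.46, the cyclin gene Ccnd3 -1.44, the splicing factor gene Srsf4 -1.29, and the lipase gene Pnpla3, Rhebl1 and the chromatin remodeler gene Atrx -1.28 each. The rule for named genes required both KO libraries to lie on the same side of both Het libraries. This was so for 60.9% of all tested genes and for 33.3% of splits by chance.

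Of the lists, 3 of housekeeping genes had the largest medians in mRNA. Of 75 cytosolic ribosomal protein genes 50 rose and 0 fell (56 rose adjusted over the list alone), with a median log2 change of 1.66. Rps27a rose by 4.56, Rpl5 by 4.36 and Rps13 by 4.26. The camera adjusted p was 1.29e-15, and 0.505 with an estimated correlation. Of 71 respiratory chain genes 47 rose (59 rose and 1 fell adjusted over the list alone), with a median of 1.65, and Cox7b rose by 4.53, Ndufc2 by 3.77 and Ndufb3 by 3.32. Its adjusted p was 2.70e-14, and 0.523 with an estimated correlation. Of 33 proteasome genes 21 rose (21 rose and 2 fell adjusted over the list alone), with a median of 1.57, and Psma6 rose by 2.65 and Psmb2 by 2.63 (adjusted p = 5.25e-06, and adjusted p = 0.523 with an estimated correlation). Maturation-activated maternal mRNAs lay lower as a list, with a median of -0.68 over 20 members (adjusted p = 3.08e-05, and adjusted p = 0.523 with an estimated correlation). In it Obox5 alone passed, with a log2 change of -1.02, and did not with median scaling, while Cdc20 had -0.98 (adjusted p = 0.0551) and Orc6 -0.79 (adjusted p = 0.107). Adjusted over the list alone 0 of its members passed in limma, with 6 at an unadjusted p under 0.05. The chromatin list had a median of -0.22 with 0 of 23 members passing in limma, also adjusted over the list alone, and 1 at an unadjusted p under 0.05 (list adjusted p = 0.0366, and adjusted p = 0.733 with an estimated correlation), and its lowest member p belonged to Dnmt3a, with a log2 change of -0.82 (adjusted p = 0.113). With the replicate block the chromatin list did not pass (camera adjusted p = 0.0513).

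In the other lists single members rose in mRNA while the list did not pass. Of the oocyte growth and zona list 6 of 14 rose (7 rose and 1 fell adjusted over the list alone, list adjusted p = 0.281), among them the zona pellucida genes Zp3 by 3.42 and Zp2 by 2.84 and the transcription factor genes Figla by 3.53 and Nobox by 2.80. Of the subcortical maternal complex list 5 of 17 rose (6 adjusted over the list alone, adjusted p = 0.0982), including Nlrp2 by 2.13 and Tle6 by 2.06. Of RNA storage factors 6 of 19 rose (7 adjusted over the list alone, adjusted p = 0.449), with Zar1l at 4.31, Cirbp at 2.01 and Rbpms2 at 1.86. Of deadenylation and decay genes 3 of 24 rose, also adjusted over the list alone (adjusted p = 0.281), namely Tob1 by 2.79, Btg2 by 1.73 and Cnot9 by 1.35. Of polyadenylation factors 3 of 17 rose (2 adjusted over the list alone, adjusted p = 0.281), namely Cpsf4, Cpsf3 and Cstf3. Of meiotic genes 7 of 32 rose (7 rose and 1 fell adjusted over the list alone, adjusted p = 0.367), with Cdc25c at 2.41, Bub1 at 2.21 and Birc5 at 2.02. Of translation factors 6 of 32 rose (7 adjusted over the list alone, adjusted p = 0.659), with Eif3g going from 4.44 to 65.6 FPKM and Eef1a1 at 2.58. In the 2-cell list (5 genes) Arg2 rose by 3.54, also adjusted over the list alone (list adjusted p = 0.242). Of 4 follicle cell markers Krt8 rose, also adjusted over the list alone, at 0.676 ± 0.218 against 2.30 ± 0.112 FPKM, and of 2 blood markers 0 passed in limma, with 0 at an unadjusted p under 0.05. Krt8 and Cstf3 did not pass with quantile normalization, median scaling or a pseudocount of 0.1, nor Cnot9 with quantile normalization. In the decay, polyadenylation and meiotic lists the median lay below 0 and the mean above 0.

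The excess of rises in mRNA depends on how libraries are scaled and on the replicate block. As deposited, 96.8% of changed genes were higher in KO and the median log2 change of all genes was 0.14. Median scaling kept the excess, with 1384 rises and 90 falls (93.9% higher) and a median of all genes of 0.04. With quantile normalization 1104 genes rose and 698 fell (61.3% higher), 1156 of them among the 1732 as deposited, and the median of all genes was -0.22. With the replicate block 3033 genes rose and 1553 fell (66.1% higher), with all 1732 among them. Relative to the median of all genes, ribosomal protein genes stood at 1.53, 1.52 and 1.52 as deposited, with median scaling and with quantile normalization, respiratory chain genes at 1.51, 1.49 and 1.56, proteasome genes at 1.43, 1.41 and 1.45, and maturation-activated mRNAs at -0.81, -0.84 and -0.61. Without a filter on low values 26 of the 50 ribosomal protein, 20 of the 47 respiratory chain and 9 of the 21 proteasome calls passed, as did 1 of 6 RNA storage, 2 of 7 meiotic, 3 of 6 translation factor, 3 of 5 subcortical maternal complex and 4 of 6 oocyte growth calls. In all 560 genes passed, and the 10 named falls, Btg2, Cdc25c, Cirbp, Cnot9, Cpsf3, Cstf3, Eef1a1, Krt8, Obox5, Rbpms2 and Tle6 did not. The 55 falls were 34 without Het library 1, 270 without Het library 2, 94 without KO library 1 and 22 without KO library 2. Rhebl1 did not pass without any one of these libraries, Atrx, Ccnd3 and Srsf4 not without Het library 1 or KO library 2, Steap2 not without Het library 1 or KO library 1, Pnpla3 not without KO library 2 and Zfp979 not without KO library 1.

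**Figure D3:**
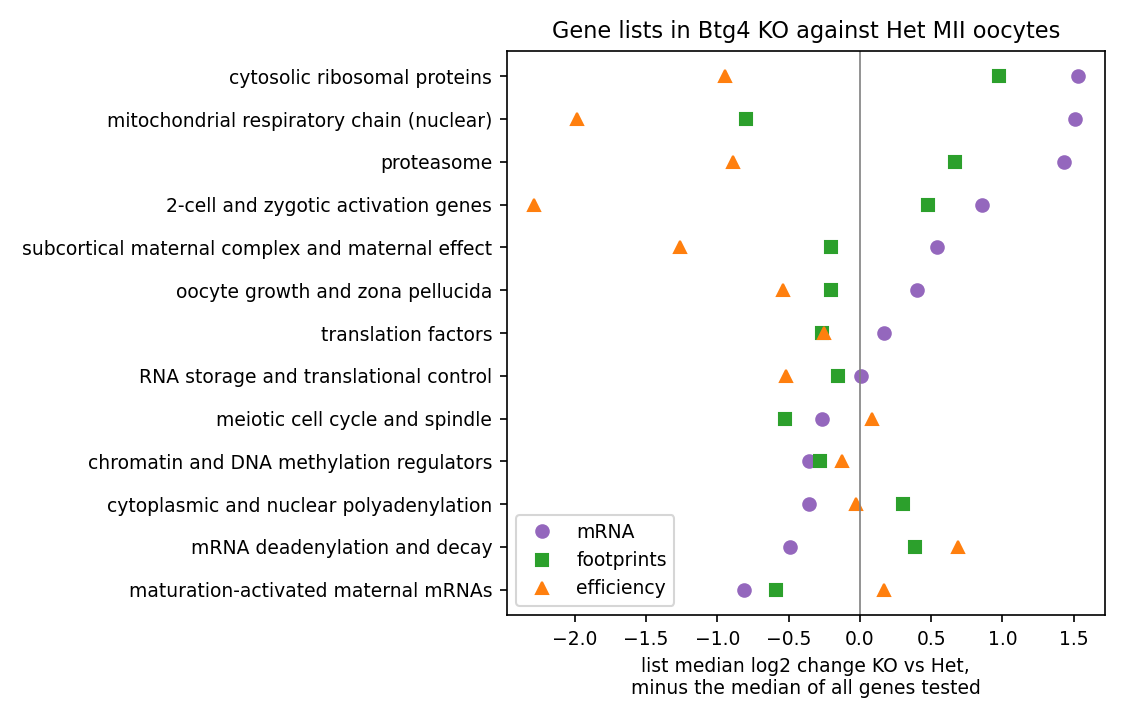
Median log2 change of KO against Het MII oocytes for 13 gene lists, minus the median of all genes tested, in mRNA, footprints and efficiency, with 1 symbol per list and assay. Respiratory chain genes stand at 1.51 in mRNA, -0.80 in footprints and -1.99 in efficiency.

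Footprints were compared next, to ask whether the changed messages were also translated more. In KO oocytes 274 of 8526 genes rose and 28 fell (limma, adjusted p below 0.05, n = 3 each). Cenpq, a kinetochore gene, rose from 2.10, 4.09 and 0 FPKM to 478, 496 and 354 FPKM (adjusted p = 0.00654). Thap1 rose from 5.87, 5.77 and 0 FPKM to 298, 444 and 278 FPKM, and the tRNA synthetase cofactor gene Eef1e1 from 0, 0 and 20.2 FPKM to 256, 503 and 420 FPKM. The vesicle transport gene Bet1 rose to 220.5 ± 11.6 FPKM (SD, n = 3), Ccdc115 to 377, 252 and 284 FPKM and Cldnd1 to 102, 158 and 203 FPKM, and each of these 3 genes was listed at 0 in 2 Het libraries. The antiproliferative gene Btg2, a relative of Btg4, was listed at 0 in all 3 Het libraries and at 41.8, 160 and 96.6 FPKM in KO. Bbip1 (73.8, 418 and 251 FPKM in KO), Sptssb (98.5, 214 and 100 FPKM) and Tctex1d2 (89.0, 203 and 73.9 FPKM) were also listed at 0 in every Het library. Among the falls, the kinase gene Stk25 had a log2 change of -4.47 (SE 0.52, adjusted p = 0.0139), Cdc42ep2 -3.89, the ribosome biogenesis factor gene Eif6 -3.68 and the cyclin-like Ccno -2.70. Plekhg3 measured 12.5, 27.2 and 21.2 FPKM in Het and 0, 2.11 and 1.22 FPKM in KO. Cenpx, another kinetochore gene, measured 150, 345 and 64.4 FPKM in Het and was listed at 0 in every KO library. Scand1 (22.4, 77.0 and 43.2 FPKM in Het), Rpp25l (13.1, 43.0 and 11.3 FPKM), Nfil3 (8.51, 20.9 and 32.8 FPKM) and Akt1s1 (6.93, 21.7 and 36.4 FPKM) were likewise listed at 0 in KO.

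Several maternal regulators gained footprints. Dazl, an RNA-binding translation activator of germ cells, rose from 378 ± 97.6 to 1695 ± 352 FPKM (log2 change 2.17, SE 0.32, adjusted p = 0.0223). The deadenylase gene Cnot6l rose by 2.18, the decapping enzyme gene Dcp2 rose from 3.55, 0 and 0 FPKM to 30.0, 40.9 and 40.8 FPKM, and with the fall of Btg4 these make 3 rises and 1 fall among 20 maturation-activated mRNAs (3 and 2 adjusted over the list alone). Of deadenylation and decay genes 5 of 23 rose (6 rose and 1 fell adjusted over the list alone), which are Btg2, Tob2, Cnot6l, Dcp2 and Cnot3. Of proteasome genes 6 of 34 rose (7 adjusted over the list alone), with Psmc6 at 3.98, Psma7 at 3.95, Psmb1 at 3.92 and Psmd12 at 3.72. The growth factor gene Bmp15 rose by 2.68 (1 of 14 in its list, 2 adjusted over the list alone). Among RNA storage factors Pabpn1l rose by 2.55 and Dazl rose, and Eif4e1b had a log2 change of -1.85 (2 rose and 1 fell of 19, 4 and 4 adjusted over the list alone). In the subcortical maternal complex list Gclm rose from 2.03, 0 and 0 FPKM to 14.7, 39.0 and 37.5 FPKM and Zbed3 changed by -1.84 (17 members, 4 rose and 4 fell adjusted over the list alone). Ccnb3 rose by 3.49 among 30 meiotic genes (2 adjusted over the list alone). Among 32 translation factors Eif3e rose from 4.44, 0 and 0 FPKM to 117, 55.5 and 86.8 FPKM, and Etf1 from 0 in every Het library to 28.8, 16.0 and 16.8 FPKM (2 adjusted over the list alone). Of 76 ribosomal protein, 68 respiratory chain, 15 polyadenylation, 21 chromatin, 7 follicle cell and 1 blood genes and of 5 genes in the 2-cell list 0 passed in limma, also adjusted over the list alone. In the same order 4, 12, 2, 2, 0, 0 and 1 of them had an unadjusted p under 0.05. As a whole 0 lists passed with camera, and 1, the respiratory chain, had an unadjusted p under 0.05. That list had a median of -0.53 (adjusted p = 0.0938), ribosomal proteins had 1.25 (adjusted p = 0.545), and the other lists had adjusted p between 0.276 and 0.990. Median and mean differed in sign in the maturation, meiotic and chromatin lists, and median and camera direction in the subcortical maternal complex, RNA storage, translation factor and 2-cell lists.

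Without any one of the 3 KO libraries 0 genes passed in footprints with limma (1200, 1315 and 1199 at an unadjusted p under 0.05, against 1549 with all libraries). Without Het library 2 or 3 the count was 154 or 86, and 0 of the 20 named genes passed in every setting. Akt1s1, Plekhg3, Cnot3, Gclm, Psmd7 and Zbed3 no longer passed with the replicate block, and these 6 with Ccnb3 and Psmd12 no longer with quantile normalization. With a pseudocount of 0.1 Bet1, Ccdc115, Cldnd1, Eef1e1, Thap1, Plekhg3, Dcp2, Eif3e, Gclm, Pabpn1l, Psmd7, Tob2 and Zbed3 did not pass, and without a filter Akt1s1, Ccdc115, Eef1e1, Nfil3, Plekhg3, Rpp25l, Dcp2, Eif4e1b, Gclm, Pabpn1l, Psmd7 and Zbed3 did not.

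Translational efficiency, the footprint change relative to the mRNA change, rose for 63 of 7382 genes and fell for 33. The vacuolar ATPase gene Atp6v1a rose by 6.30 on the log2 scale (SE 0.75, adjusted p = 0.0144), the chromatin organiser gene Satb1 by 6.23, Synj2bp by 6.01, the cyclin gene Ccnl1 by 5.72, the replication fork gene Timeless by 5.59, Fndc3a by 5.55 and the initiation factor gene Eif3e by 5.54. Bbip1, the signal recognition particle gene Srp19 (39.6, 48.9 and 53.7 FPKM in KO) and Nrbf2 (58.8, 26.9 and 65.8 FPKM) had footprints listed at 0 in every Het library. Pdpn had a log2 change of -6.26 (SE 1.19, adjusted p = 0.0440), Eif6 -5.62, Psmb7 -5.47, the arginase gene Arg2 -5.44, the mitochondrial glutaredoxin gene Glrx5 -5.34, Cdc42ep2 -5.27 and the spindle-associated Nudc -5.13. For Cenpx, Scand1 and Csrnp2 (0.90, 1.77 and 4.63 FPKM in Het) the KO footprints were listed at 0. Atp6v1a, Satb1, Synj2bp, Timeless and Eif3e were listed at 0 in 1 or 2 Het footprint libraries and Pdpn in 2 KO ones, so the sizes of these changes depend on the pseudocount. Psmb7 had mRNA at 2.00 ± 0.231 against 291 ± 22.7 FPKM and footprints at 24.4 ± 18.8 against 48.1 ± 18.3 FPKM.

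Several lists had lower efficiency in KO. Efficiency is relative to the measured polyadenylated mRNA, whose median log2 change was 1.65 for respiratory chain and 1.66 for ribosomal protein genes. Whether tail length affects the capture of mRNA is left open below, so these values need not measure translation per message. The respiratory chain list had a median of -1.75 over 67 genes (camera adjusted p = 6.20e-10, and adjusted p = 0.524 with an estimated correlation), and in it Ndufa1 fell by 3.41 (3 fell adjusted over the list alone). Ribosomal proteins had a median of -0.71 over 74 genes, of which 0 passed in limma, also adjusted over the list alone, and 2 had an unadjusted p under 0.05 (list adjusted p = 0.0262, and adjusted p = 0.805 with an estimated correlation). The subcortical maternal complex list had a median of -1.02 over 17 genes (adjusted p = 0.0102, and adjusted p = 0.617 with an estimated correlation), and Tle6 fell by 3.29 in it (1 rose and 3 fell adjusted over the list alone). Deadenylation and decay genes had a median of 0.93 over 23 genes (adjusted p = 0.0183, and adjusted p = 0.704 with an estimated correlation), with Btg2 rising and 5 rising adjusted over the list alone. These 4 lists kept their sign relative to all genes under both other scalings. Proteasome genes had a median of -0.65 (33 genes, adjusted p = 0.0867), where Psma7 rose by 3.96 and Psmb7 fell (4 and 4 adjusted over the list alone). Maturation-activated mRNAs had a median of 0.41 (20 genes, adjusted p = 0.129), with Dazl rising by 2.51 (3 rose and 1 fell adjusted over the list alone). RNA storage factors (19 genes, adjusted p = 0.427) had Dazl rising, with 1 rise and 2 falls adjusted over the list alone. Meiotic genes (30 genes, adjusted p = 0.892) had Ccnb3 rising by 4.27, also adjusted over the list alone, and translation factors (32 genes, adjusted p = 0.852) had Eif3e and Etf1 rising, with 2 rises and 2 falls adjusted over the list alone. In the meiotic and translation factor lists the median and the mean differed in sign. Of 14 oocyte growth, 15 polyadenylation and 21 chromatin genes (adjusted p = 0.694 for each list) 0 passed in limma, with 5, 1 and 1 at an unadjusted p under 0.05, and adjusted over the list alone 2 growth genes rose and 1 fell. In the 2-cell list (2 genes) Arg2 fell, also adjusted over the list alone, and of 3 follicle cell and 1 blood markers 0 passed in limma, with 1 and 0 at an unadjusted p under 0.05.

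With the replicate block 49 efficiency changes passed in place of 96, and Arg2, Cdc42ep2, Csrnp2, Eif6, Pdpn, Satb1, Scand1, Timeless, Btg2, Ccnb3, Dazl, Etf1 and Psma7 were not among them. With a pseudocount of 0.1 Atp6v1a, Eif3e, Pdpn, Satb1 and Timeless did not pass, without a filter Cdc42ep2, Csrnp2, Eif3e, Pdpn, Satb1, Timeless, Btg2, Ccnb3, Dazl, Etf1, Ndufa1 and Tle6 did not, and with quantile normalization Csrnp2, Btg2 and Ccnb3 did not. Without any one of the 4 mRNA libraries 0 passed with limma (614 to 714 at an unadjusted p under 0.05, against 1034 with all libraries), and without Het footprint library 1 the count was 203, without KO footprint library 2 it was 49 and without library 3 it was 46.

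Of 7382 genes tested in both assays, 1365 rose in mRNA and 270 in footprints, with 100 in both against 49.9 if the calls were independent (one-sided Fisher's exact test, p = 1.95e-13, over genes that are not independent). Another 6 rose in mRNA and fell in footprints, against 4.99. The 1365 genes that rose in mRNA had a median log2 change of 1.79 in mRNA and 0.89 in footprints, and 66.6% of them had a footprint change above 0, against 58.3% of all genes. Across genes the mRNA and footprint changes had a Spearman rho of 0.193.

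Poly(A) tails were compared because Btg4 recruits a deadenylase. Over the 129 genes measured in all 5 libraries the median tail was 57.1 nt in FGO wild type, 44.9 nt in MII wild type, 64.5 nt in MII Het, and 56.8 and 57.6 nt in the MII KO libraries. KO minus Het had a median of -3.70 nt (quartiles -17.5 and 13.6), with 42.6% of genes longer in KO. It was -6.35 nt without KO library 1, -5.64 nt without KO library 2, and -9.21 nt over the 272 genes measured in the Het and KO libraries. Against MII wild type the KO median was 11.2 nt longer, with 68.2% of genes longer, so the direction depends on the control. Both control arms have 1 library each. Over the 636 genes measured in both KO libraries, these differed by a median of 0.09 nt, with a Spearman rho of 0.687. Gene by gene they lay further apart, with a median SD between the KO libraries of 7.54 nt over the 129 genes. The KO minus Het median of -3.70 nt is smaller than this SD. With limma 0 genes passed in either contrast (23 and 25 at an unadjusted p under 0.05), in a fit that called 3% of simulated shifts of 40 nt, and the values below did not pass. Tails of H3f3b, a histone gene, measured 47.7 nt in Het and 118 and 88.7 nt in KO. Parp12 measured 68.9 nt against 113 and 112 nt, Trim61 75.7 nt against 112 and 110 nt, Oosp1 73.5 nt against 97.2 and 128 nt, and Pcbp1 67.6 nt against 130 and 98.9 nt. The KO libraries lay further apart for Mat2b (66.3 nt against 92.6 and 159 nt), Rae1 (45.8 nt against 130 and 76.2 nt), Jag1 (52.3 nt against 76.5 and 99.1 nt) and Rbm38 (105 nt against 111 and 171 nt). The KO mean of each of these 9 genes was also above MII wild type. Shorter in KO than in Het were the splicing regulator gene Ptbp1 by -110 nt, Mtus1 by -73.3 nt, Tbc1d22b by -66.9 nt, Bcl2l10 by -57.6 nt, Ninj1 by -52.8 nt, Hif1a by -40.1 nt (107 nt against 49.7 and 84.3 nt), the meiotic kinase gene Mos by -39.2 nt and Tet3 by -37.5 nt. Against MII wild type the KO mean was longer for Ptbp1 (54.5 nt in wild type, 61.9 nt in KO), Hif1a (44.9 and 67.0 nt) and Mos (73.6 and 89.1 nt), close for Ninj1 (32.0 and 31.0 nt), and shorter for the other 4, among them Tet3 (149 and 68.9 nt).

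**Figure D4:**
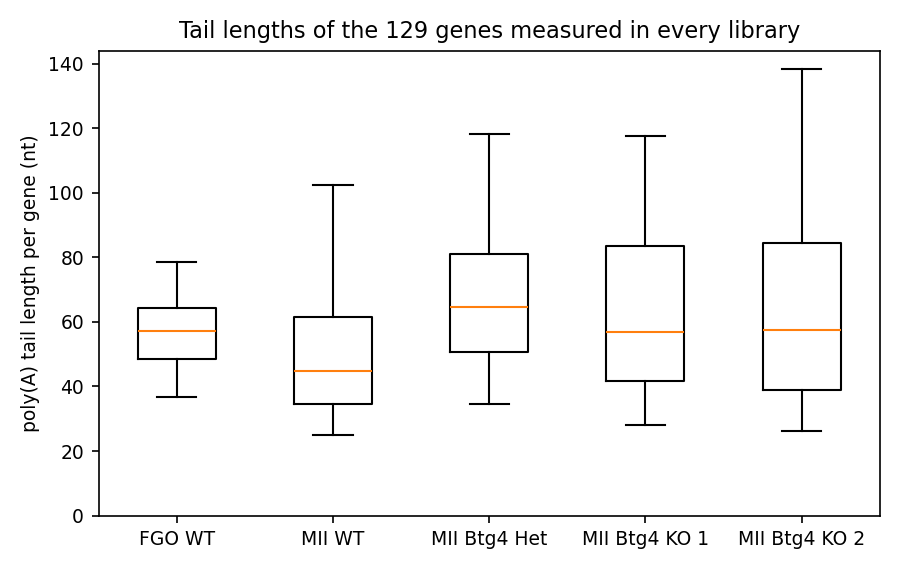
Poly(A) tail length in nt of the 129 genes with a value in every tail library, with boxes from the lower to the upper quartile, a line at the median and whiskers from the 5th to the 95th percentile of genes. Medians are 57.1 nt (FGO wild type), 44.9 nt (MII wild type), 64.5 nt (MII Het) and 56.8 and 57.6 nt (MII KO).

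From FGO to MII in wild type, tails changed by a median of -8.50 nt (quartiles -25.2 and 9.65), with 36.4% of the 129 genes longer, 1 library per stage and 0 genes past the threshold in limma (24 at an unadjusted p under 0.05). With the Het library as the MII arm, a comparison added after seeing the data, the median was 8.15 nt. Among the largest gains were the remodeler gene Arid1a, which is outside the chromatin list, at 41.2 nt in FGO and 192 nt in MII, H1foo at 60.1 and 172 nt, Tet3 at 45.9 and 149 nt, the maintenance methyltransferase gene Dnmt1 at 59.7 and 161 nt, and Ezh2 at 50.8 and 87.7 nt. In the Het library Arid1a measured 75.3 nt and Dnmt1 69.3 nt. Bpgm, Usp19, Bcl2l10 and Rbm38 were longer by 63.4, 54.6, 48.4 and 37.6 nt. Tcl1 was longer by 60.9 nt, but its KO libraries differed widely, at 340 and 88.9 nt. Among the losses were Eif1b at 89.4 and 25.0 nt, Mgst3 at -52.5 nt, the ubiquitin gene Ubb at -45.9 nt, the peroxiredoxin gene Prdx1 at -45.5 nt, Rnf114 at -42.2 nt, Fbxw18 at -40.9 nt, Gyg at -40.8 nt and the ribosomal protein gene Rps15a at -39.7 nt. Among the lists with at least 4 genes, chromatin regulators had a median of 101 nt (5 genes, 4 longer, with Uhrf1 at -18.3 nt), maturation-activated mRNAs 17.1 nt (4 genes, 3 longer), oocyte growth genes 11.6 nt (6 genes, 3 longer), meiotic genes 5.16 nt (4 genes, 2 longer), the subcortical maternal complex -21.3 nt (6 genes, 1 longer) and RNA storage factors -32.4 nt (4 genes, 0 longer). With the Het library the medians were 33.3 nt for chromatin (10 genes, 10 longer), 70.6 nt for maturation-activated mRNAs (10 genes, 9 longer), 22.8 nt for oocyte growth (8 genes, 5 longer), 71.1 nt for meiotic genes (6 genes, 4 longer), -21.5 nt for the subcortical maternal complex (8 genes, 3 longer) and -2.59 nt for RNA storage factors (6 genes, 3 longer).

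Tail and footprint changes went together across genes. From FGO to MII the tail change and the single-oocyte footprint change had a Spearman rho of 0.587 over 220 genes. No wild-type mRNA was analysed here, so this footprint change can come from the amount of mRNA as well as from its translation. In KO against Het the tail change had a rho of 0.34 with the footprint change, 0.396 with the efficiency change and -0.123 with the mRNA change, over 265 genes. With MII wild type as control, a comparison added after seeing the data over 150 genes, these were 0.279, 0.425 and -0.299. They belong to a family of 7 relations computed across genes.

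The Btg4 effect was then ordered by what messages did during normal maturation. Across 7739 genes the footprint change from FGO to MII had a Spearman rho of -0.562 with the KO change in mRNA. Of 778 genes whose footprint log2 ratio was at most -2, 49.1% rose in mRNA in KO, with a median log2 change of 1.22, and 2 fell. Of 1145 genes with a ratio above 2, 1.66% rose, 23 fell, and the median was -0.60. The correlation was -0.167 for the KO change in footprints (7583 genes) and 0.19 for efficiency (6882 genes), which shares the mRNA libraries and was 0.0969 with a pseudocount of 0.1. In footprints the median KO change went from 0.69 in the lowest group to -0.18 in the highest, and in efficiency from -0.63 to 0.42.

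**Figure D5:**
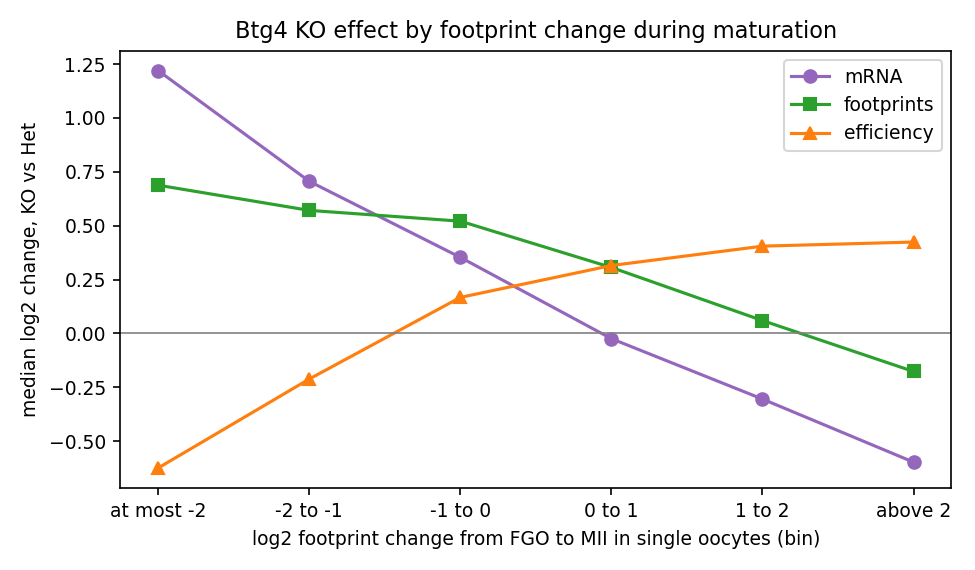
Median log2 change of KO against Het MII oocytes in mRNA, footprints and efficiency for genes grouped by their log2 footprint change from FGO to MII in single oocytes. The mRNA median goes from 1.22 in genes at most -2 to -0.60 in genes above 2.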

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

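The tests on scaling, on different genes, on a whole-library shift, on oligo-dT capture and on other splits were chosen after the results were seen. The outcomes expected of the tests on depth and on low-level genes were set before the values they measure were seen, although the thinning used for depth was itself added after seeing the data.

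The first pattern is that 274 footprint calls were higher in Btg4 KO and 28 lower. The library with the fewest recovered reads was a Het one. With the 6 libraries thinned to 60850 reads each, 87.7% of calls were higher in KO (83.1 to 89.6 over 10 thinnings, 88.3% without thinning). For the 4116 to 4160 genes tested after thinning (8526 in the main fit), this argues against the number of reads as the whole cause. Thinning does not equalise the genes found at a given depth. Het library 2 listed 5903 genes at 1 FPKM or more with 101859 recovered reads, and KO library 1 listed 8398 with 100281. A part of such a difference in the rises stays open. With median scaling 87.3% were higher, although it moved the median of all genes only from 0.27 to 0.25. With quantile normalization, which moved that median to -0.14, 86.1% were higher. Together these values argue against a scale set by a few abundant genes. Of the 10 splits of the 6 libraries 1, the real one, gave as many genes (302, the highest other 18, and 0 among the other splits that part all 3 pairs), and 10 splits are too few for a share under 0.05. A direct effect of the genotype stays open, as does a difference in total RNA, which FPKM cannot show.

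The second pattern is that the sign of the KO tail difference depends on the control, with -3.70 nt against Het and 11.2 nt against MII wild type. The change from FGO to MII also differed in sign, with -8.5 nt for the wild-type library and 8.15 nt for the Het library, and this difference between the genotypes was not tested as a whole (limma found 0 genes between Het and wild type, 23 at an unadjusted p under 0.05). All of these medians are over the same 129 genes, so different sets of measured genes cannot be the source of these differences in sign. Over these 129 genes Het exceeded wild type by a median of 15.8 nt. A shift of a whole library may be the source, as 77.5% of genes were longer in Het, but with 1 library per genotype this cannot be told apart from an effect of the genotype.

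The third pattern is the rho of -0.562 between the footprint change in maturation and the mRNA change in KO. Noise at low levels is argued against, since rho was -0.598 and -0.662 in the upper 2 quintiles of mRNA level and -0.381 in the lowest. Better capture of lengthened tails by oligo-dT could raise mRNA values without any change in mRNA amount. The rho of tail and mRNA change was -0.123, but only 26 of the 1677 mRNA rises (1.55%) have a tail change, so this stays open. A direct effect of the genotype stays open as well, and was not tested.

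Outside the comparisons, 1505 genes had a tail length in the authors' merged KO column and none in their merged wild-type and Het column.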

How the results depend on the processing

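The filter at 50 FPKM, the thinned reads, the Het library as MII arm, wild type as control for tail correlations, the removal of oocytes with hemoglobin and that of MII oocytes 2 and 4 were added after seeing the data. Causes were not tested except where fewer libraries or genes enter.

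The mRNA count of 1732 was 560 without a filter and 1161 to 1843 with each library left out, where the lone library is assumed to vary like the others. With the replicate block it was 4586 (3033 higher, 1553 lower). The mRNA libraries share only a number. With 2 libraries per genotype the deviations mirror each other, so the correlation was 0.627 for the same number and -0.627 for different numbers. This is a single value, although it also lies over 0.1, so whether the mRNA libraries are paired stays open. The footprint count of 302 was 199 with a pseudocount of 0.1, 157 without a filter, 173 with quantile normalization (median of all genes -0.14 in place of 0.27), 180 at 50 FPKM or more, 132 with thinned reads (179 for the same genes unthinned) and 0 to 274 with each library left out. It was 267 with the replicate block. The efficiency count of 96 was 39 without a filter, 169 with median scaling, 49 with the replicate block, 47 at 50 FPKM or more and 0 to 203 with each library left out. The Results name the genes whose calls the block ended. Of 9 list calls 0 passed with an estimated correlation. Fry, which does not compare with other genes, passed 3 of all the lists tested. These were the mRNA lists of ribosomal proteins and oocyte growth (fry adjusted p = 0.0185 each) and the proteasome (fry adjusted p = 0.0319). Oocyte growth was not among the 9 calls (camera adjusted p = 0.281).

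The KO tail difference of -3.70 nt was 11.16 nt with MII wild type as control and -6.35 to -5.64 nt with each KO library left out. The FGO to MII difference of -8.50 nt was 8.15 nt with the Het library. No paired analysis was possible because tail arms have 1 library and oocyte numbers only name cells. Reads per gene are not in the tail table, so the minimum of 20 reads was not run, and 0 oocytes had too few genes for the planned removal, which gave no value. Without oocytes that list hemoglobin, the single-oocyte median was 0.0440 and the blood list 0.19, a move partly fixed by that selection. With medians over oocytes, the subcortical maternal complex and the oocyte growth lists lay at percentiles 3.28 and 5.11 and the blood list at 73.3, and with median scaling the oocyte growth list at 2.70.

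With Pearson's r, the tail correlations were 0.275 (footprints), 0.3 (efficiency) and 0.51 (FGO to MII), and that of maturation with KO mRNA was -0.513. Without MII oocytes 2 and 4 the latter had a rho of -0.573 and the FGO to MII tail correlation one of 0.591. Against wild type the tail and mRNA value was -0.299. With a pseudocount of 0.1, maturation gave -0.538 (mRNA) and 0.0969 (efficiency), and at 10 FPKM or more -0.695 (mRNA), -0.217 (footprints) and 0.233 (efficiency). Over all alternatives for single genes and lists, 959 values were counted as the same, 278 lost the threshold, 8 gained it, 43 moved and 1 reversed. Among alternatives for the main counts, medians and correlations, 57 were counted as the same, 35 moved and 3 reversed. For lists and for tails of single genes, a change of sign counted as a reversal only where the main result was past its threshold. Changes of sign can therefore also lie among the values counted as the same or moved. Spread and depth limit footprints and efficiency, where simulated 8-fold changes were called in 26 of 66 and 1 of 66 genes.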

Other observations

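The counts by merged column and the values with the Het library as the MII arm were chosen after the data were seen. Genes with a tail value in the authors' merged KO column alone (1505 genes) had a median tail of 39.3 nt, and 471 of the 1485 that were tested rose in mRNA in KO (31.7%), with a median log2 change of 0.62. Their median footprint log2 ratio from FGO to MII was -0.62. The 660 genes with a value in both merged columns had medians of 57.9 nt (KO) and 60.2 nt (wild type and Het), and 62 of 658 rose in mRNA (9.42%). The 222 genes seen in the wild-type and Het column alone had a median of 75.5 nt, 5 of 220 rose, and their median footprint ratio was 1.54. The table gives no reads per gene.

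With the Het library as the MII arm more list members had a tail value. Of 10 maturation-activated mRNAs 9 were longer in MII, with a median of 70.6 nt, from -7.46 nt in Tpx2 to 126 nt in Obox5. Of 10 chromatin regulators 10 were longer, with a median of 33.3 nt and the largest gain in H1foo at 90.7 nt. Of 8 subcortical maternal complex genes 3 were longer, with a median of -21.5 nt and the largest loss in Tle6 at -36.6 nt. Of 5 deadenylation and decay genes 5 were longer, with a median of 40.0 nt. Meiotic genes had 71.1 nt (6 genes, 4 longer), oocyte growth genes 22.8 nt (8 genes, 5 longer), proteasome genes 12.8 nt (5 genes, 3 longer) and translation factors -1.45 nt (4 genes, 2 longer). Against the same Het library, the 4 respiratory chain genes measured in KO had a median of -24.6 nt and 0 were longer, and the 3 proteasome genes had -20.9 nt and 0 were longer. The lists of chromatin (-18.7 nt, 1 of 6 longer), oocyte growth (-16.4 nt, 2 of 7), the subcortical maternal complex (-10.8 nt, 2 of 8), meiotic (-6.08 nt, 2 of 4), maturation-activated (5.06 nt, 3 of 4) and RNA storage genes (15.6 nt, 2 of 4) lay between -18.7 and 15.6 nt. The control arms are single libraries, the KO arm is the mean of 2, and no list was tested.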
